A study of Mus musculus with 4 samples.

How the data were processed

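Gene expression was measured in 4 samples of mouse neural stem cells on Affymetrix expression arrays, 1 array per sample. Per the labels, the cells were taken from the ganglionic eminences, the ventral forebrain zones that give rise to interneurons and to early oligodendrocyte precursors, of embryos at embryonic day 14.5. They were grown in serum-free medium with EGF, and the genetic background was C57/Bl6. Total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it, per the labels' protocols. The genotype label put 1 sample in the wild-type group and 3 in the Olig1 KO group. The titles number 2 of the KO samples, 37 and 38, which are called replicates 2 and 3 here, and the unnumbered one is replicate 1. The labels do not say whether the KO samples came from separate embryos or cultures, so the p-values measure only the spread between these samples, which may be technical.

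The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array; MAS5 is named in the submitters' processing notes, and its version and scaling target are not given in the sources used here. In each array as deposited, the mean after removing 2% of probe sets from each tail was about 500.2, so the authors had scaled every array by 1 factor. No detection calls were used here. Negative or zero intensities did not occur. The table held 22690 probe sets, of which 64 were Affymetrix controls. A table of the platform's annotation gave 1 gene symbol to 20393 probe sets, several to 691 and none to 1606. The 13 control probe sets with a symbol were left out of the gene test. Symbols were updated through the gene identifiers in a RefSeq table of GRCm38.p6, in which 24 genes' identifiers were absent and kept the platform's symbol. The array table has no coordinates, so the RefSeq table served only for names, chromosomes and neighbouring genes.

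The following choices were made before the data were examined unless said otherwise. Intensities were turned into log2(signal + 14.4), where the pseudocount of 14.4 is 0.1 times the median of all values. All fold changes are on this scale, which understates the change of dim genes. No further normalization was applied, because the arrays' trimmed means differed by less than 1.25 times. Each of 12393 genes was represented by its probe set with the highest mean log2 value, and 4956 genes had more than 1 probe set. The 40% of genes with the lowest mean over the 4 arrays were left out, which kept 7436 genes.

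KO and wild type were compared with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the kept genes and a threshold of 0.05. With 1 wild-type array, the spread came from the 3 KO arrays (2 residual degrees of freedom, 5.23 prior degrees of freedom), and the wild-type array was assumed to vary like them. The number of arrays limits the precision of every value. Data were simulated with 7436 genes and this design, with 200 genes changed per run, 50 at each size. The fit recovered 2.2% of genes changed by 1 log2 unit, 54.9% of those changed by 2, 92.9% of those changed by 3 and 99.6% of those changed by 5. It called 0.0808% of the unchanged genes. Many planted changes ease the adjusted threshold, so recovery would be lower with fewer changed genes, which was not simulated.

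Of 26 gene lists fixed in advance, 17 had at least 5 kept members. They covered neural, glial, neuronal and other cell types, cell cycle, signalling, stress and metabolism. These 17 were tested with limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list's median was also placed among 10000 random lists of the same size matched on mean expression in 10 bins. In 20 simulated data sets, a list of 22 genes shifted by 0.5 log2 units was called 20 times and an unshifted one 2 times by camera at an unadjusted p under 0.05. The simulated genes were drawn independently, so these counts do not allow for genes that move together.

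Genes were named by a rule. It took Olig1 and Olig2, up to 10 genes past the threshold in each direction, and where fewer passed, genes with the wild-type array at least 1 log2 unit from every KO array, ordered by size. It also took up to 4 kept members of each list by moderated t, the sex-linked genes, called genes within 10 Mb of Olig1, and the 5 genes with the largest SD over the KO arrays. Not every list member that the rule takes is named in the text. Alternatives covered scaling, pseudocount, filter, choice of probe set, eBayes settings, a minimum fold change of 1.5, each KO array left out, the correlation in camera, fry in place of camera, which tests the genes of a list alone against no change, and the window around Olig1. A fit with the pair of arrays as a block (wild type with KO replicate 1, KO replicates 2 and 3) was added after the data were seen, also with an estimated correlation. A signal is called at background where it does not exceed the highest signal of 27 bacterial probe sets with no target on the same array. Figures were drawn with matplotlib 3.10.9.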

Results

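The series compared neural stem cells from the ganglionic eminences of wild-type and Olig1 knockout (KO) mouse embryos at embryonic day 14.5. Olig1 encodes a basic helix-loop-helix transcription factor of the oligodendrocyte lineage. The comparison asks which transcripts differ in these cultures when Olig1 is mutated. There was 1 wild-type array and there were 3 arrays labelled Olig1 KO, all scaled by the authors to a trimmed mean signal of about 500.2, with median signals between 140.8 and 146.7. Expression of stem cell genes was measured in all 4 arrays. Sox2, a neural stem cell transcription factor, gave a signal of 4073 in the wild-type array and 4146 ± 609 (SD, n = 3) in the arrays labelled KO. Egfr, the receptor for the growth factor in the medium, gave 1048 against 1088 ± 109 (SD, n = 3). Sox2 and Egfr were chosen after their values were seen, to describe the cultures.

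In the values as deposited, the targeted gene did not separate the genotypes. The only Olig1 probe set gave a signal of 7618 in the wild-type array. In the arrays labelled KO it gave 3840 in replicate 1, 4438 in replicate 2 and 8548 in replicate 3, or 5608 ± 2563 (SD, n = 3). The log2 difference of KO from wild type was -0.53 (SE 0.48, limma adjusted p = 0.99997), smaller than the range of the KO arrays. The Olig1 signal in every array labelled KO was at least 97.3 times the highest signal of 27 bacterial control probe sets that had no target. Neither the part of the gene that the allele lacks nor the position of the probe set was known here, so this signal does not check the genotype labels. The arrays are therefore called by their labels throughout, and every direction below rests on those labels. Olig2, the paralogue next to Olig1 on chromosome 16, gave 4278 in the wild-type array and 3681 ± 1147 (SD, n = 3) in the arrays labelled KO, a log2 difference of -0.26 (SE 0.40, limma adjusted p = 0.99997).

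The 4 arrays fell into pairs that cut across genotype. Xist, the noncoding RNA of the inactive X chromosome, gave 9480 in the wild-type array and 8472 in KO replicate 1, but 160.9 in KO replicate 2 and 46.5 in KO replicate 3. The Y-linked gene Eif2s3y gave 0.61 and 1.53 in the first pair and 654 and 1160 in the second. The Y-linked genes Kdm5d and Uty, left out by the filter, showed the same split. Kdm5d gave 16.4 and 20.7 against 390.7 and 232.8, and Uty gave 26.1 and 36.8 against 278.4 and 190.3. The array controls split in the same way. The median of 3 probe sets for 18S ribosomal RNA was 4.64 and 7.24 in the first pair and 946 and 2823 in the second. The 18 probe sets for spiked-in bacterial and phage transcripts were 0.90 times the wild-type array in KO replicate 1, 1.93 times in KO replicate 2 and 2.87 times in KO replicate 3. The 3'/5' signal ratio of beta-actin, a sign of RNA integrity, was 1.11 in the wild-type array and 1.251, 1.30 and 1.82 in KO replicates 1, 2 and 3. That of Gapdh did not follow this order, at 0.759 in the wild-type array and 0.794, 1.03 and 0.842 in the KO arrays. Genotype could be compared within a pair only between 2 single arrays, wild type and KO replicate 1.

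**Figure D1:**
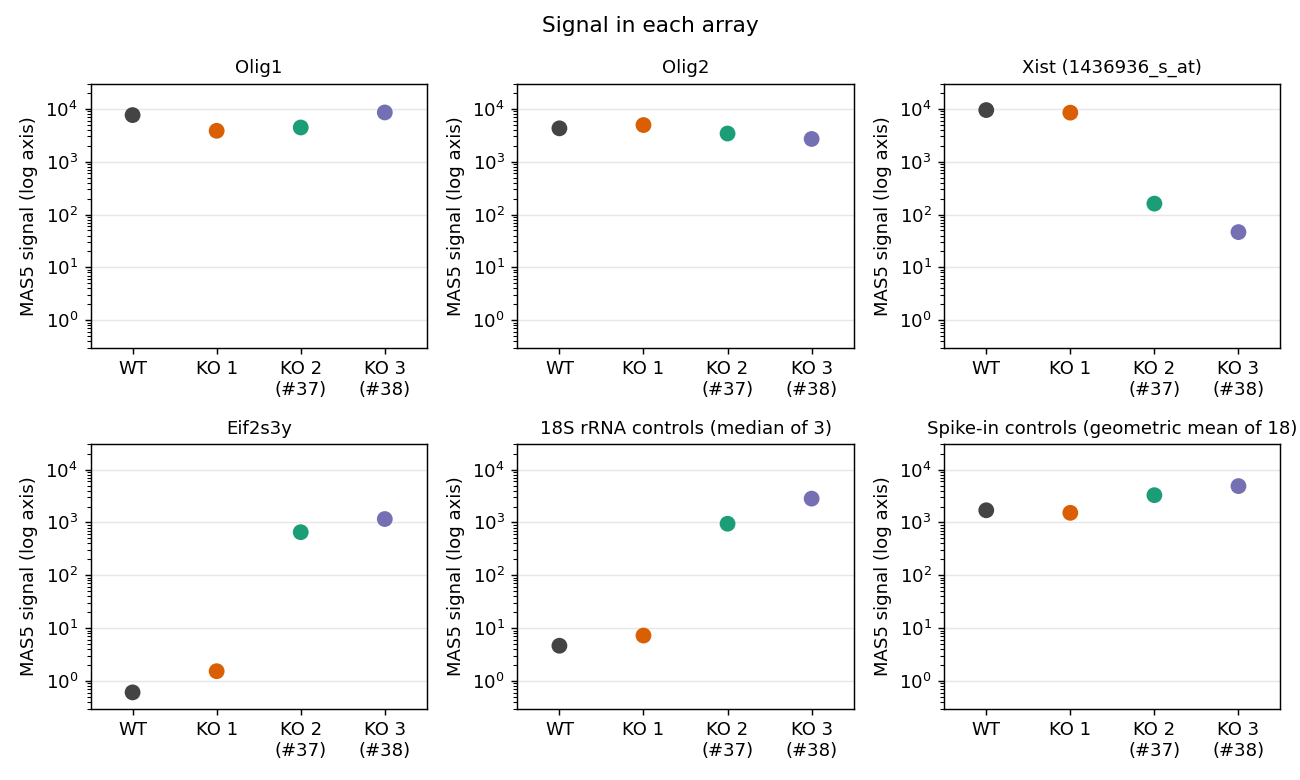
MAS5 signal (log axis) of Olig1, Olig2, Xist, Eif2s3y, the 18S ribosomal RNA controls and the spike-in controls in the wild-type array (WT) and the 3 arrays labelled KO, 1 point per array. Olig1 spans 3840 to 8548 in the KO arrays around the wild-type value of 7618, while Xist, Eif2s3y and the 18S controls separate WT and KO 1 from KO 2 and KO 3.

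Over the 7436 genes kept, the wild-type array was closer to KO replicate 1 than any KO array was to another. The SD of their log2 differences over genes was 0.36, and 139 genes (1.87%) differed at least 2-fold. Among the KO arrays, this SD was 0.46 between replicates 1 and 2, 0.51 between replicates 2 and 3, and 0.65 between replicates 1 and 3, with 241, 392 and 804 genes at least 2-fold apart. The wild-type array lay at least 2-fold from all 3 KO arrays for 21 genes, below them for 12 and above them for 9. When each KO array was set against the other 3 arrays in the same way, 23 genes stood apart in replicate 1, 17 in replicate 2 and 173 in replicate 3. With 4 arrays, such a comparison of single arrays cannot reach a share under 0.25.

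**Figure D2:**
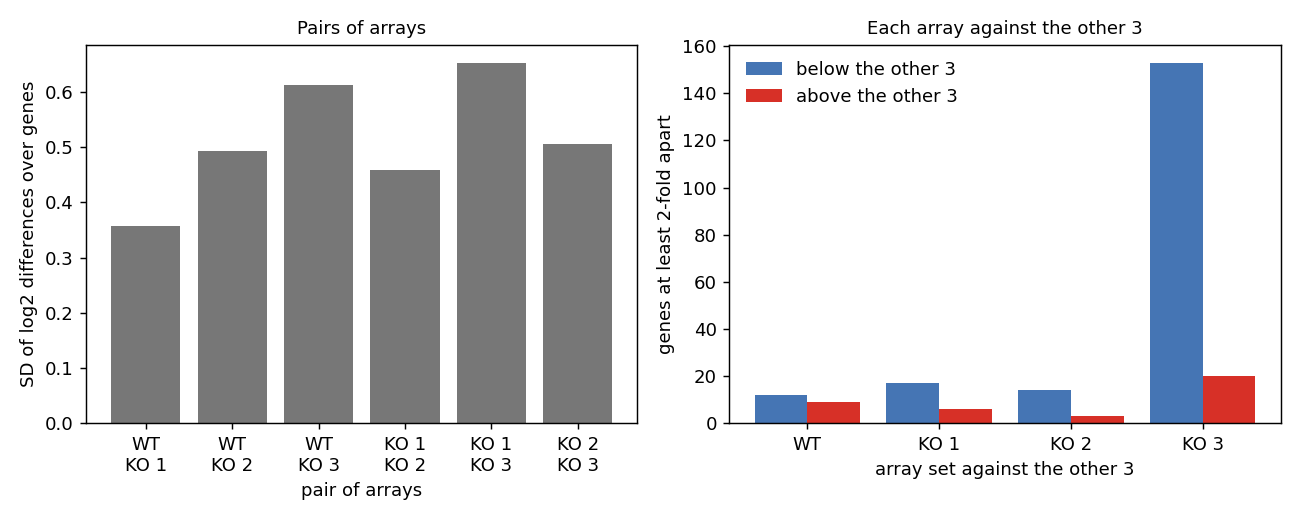
Left, SD over 7436 genes of the log2 difference between the 2 arrays of each pair; right, number of genes for which 1 array lay at least 2-fold below (blue) or above (red) each of the other 3. The wild type and KO 1 differ least (SD 0.36), and KO 3 has the most genes apart from the rest (153 below and 20 above).

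No gene passed the test for a difference between KO and wild type. In limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and 168 genes (2.26% of those kept) had an unadjusted p under 0.05, of which 98 were higher and 70 lower in the KO arrays. The wild-type array lay outside the range of the KO arrays for 3259 genes (43.8%), against 50% expected by chance for 1 array among 4. With the pair of arrays as a block, 0 genes passed and 110 had an unadjusted p under 0.05. Leaving out 1 KO array moved the count at an unadjusted p under 0.05 to 486 without KO replicate 1, 63 without KO replicate 2 and 327 without KO replicate 3. Without KO replicate 1, which left the 2 arrays of the other pair, the fit called 2 genes, Eif2s3y and Tmem87a. The design recovered 2.2% of 2-fold changes and 54.9% of 4-fold changes in simulated data with 200 changed genes per run. Differences of about 2-fold were thus not detectable at this number of arrays. With fewer changed genes the recovery of larger changes would be lower as well.

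In 12 genes the wild-type array was at least 2-fold below every KO array, and the 10 with the largest difference are given as values, since none passed the test (limma adjusted p = 0.99997 for each). The largest difference as measured, with no allowance for background, was that of Hmga2, which encodes a chromatin protein of fetal stem cells. Its signal was 58.8 in the wild-type array and 348 ± 203 (SD, n = 3) in the KO arrays, a log2 difference of 2.16 (SE 0.57). Its other 2 probe sets were at background in KO replicate 3, and 1 of them in the wild-type array as well (4.29). Airn, the imprinted noncoding RNA antisense to Igf2r, gave 171.6 ± 39.5 in the KO arrays against 30.0 in the wild-type array, which is not above the highest bacterial probe set with no target there (30.5), so its difference has no exact size. Lix1 gave 55.2 against 183.2 ± 46.6. Stard13 gave 42.1 against 143.1 ± 15.4. Dennd1a, an endocytic regulator, gave 64.6 against 166.7 ± 27.0. The other 5 named genes had further probe sets. Gpaa1, a subunit of GPI transamidase, differed by 2.09 with 1 probe set and by -0.0048 with another, while the third was at background in the wild-type array. The palmitoyltransferase gene Zdhhc14 differed by 1.80 with 1 probe set and by -0.16 to 0.18 with the 4 others above background in all 4 arrays, all 5 of them marked for cross-hybridization. Rgcc differed by 1.57 and 0.38. Hamp differed by 1.47 with a probe set marked for cross-hybridization. Its other probe set showed no rise, at 80.9 in the wild-type array and 66.0 and 72.2 in KO replicates 1 and 2, and was at background in KO replicate 3. The Notch ligand gene Jag2 differed by 1.20. Its other probe set did not show this rise, at 33.0 in the wild-type array, above background, and at background in the KO arrays.

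In 9 genes the wild-type array was at least 2-fold above every KO array, again without passing the test (limma adjusted p = 0.99997 for each). Tmem87a gave 1166 in the wild-type array, 567 in KO replicate 1, and 29.4 and 25.8 in KO replicates 2 and 3, both at background, so its difference has no exact size. Sez6 gave 288.7 in the wild-type array and 135.8, 24.6 and 100.7 in KO replicates 1, 2 and 3, at background in replicate 2. Dnah8, an axonemal dynein heavy chain gene, gave 520.0 in the wild-type array and 178.4 ± 3.25 (SD, n = 3) in the KO arrays, a log2 difference of -1.47 (SE 0.30), while its other probe set was at background in the wild-type array. Cox8b, a cytochrome c oxidase subunit gene, gave 1308 against 541.0 ± 13.6. Gpr37l1, a glial G protein-coupled receptor gene, gave 478.0 against 181.5 ± 25.02. The others were Trim35, Adam4, the progestin receptor gene Paqr7 and Kcnip1, an interactor of potassium channels, with log2 differences of -1.66, -1.45, -1.44 and -1.29. The other probe set of Sez6 differed by -0.76, and the only other probe set of Kcnip1 above background in all 4 arrays by -0.65.

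**Figure D3:**
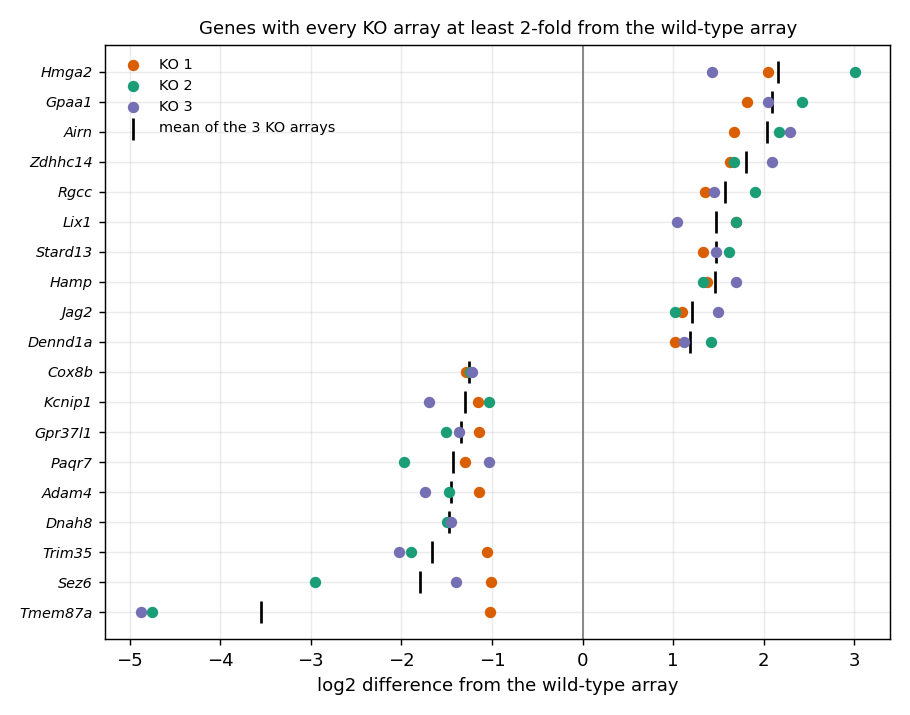
Log2 difference from the wild-type array of each array labelled KO (coloured points) and their mean (black bar), for the 19 named genes with every KO array at least 2-fold from the wild-type array. Signals were at background for Airn in the wild-type array, Tmem87a in KO 2 and KO 3, and Sez6 in KO 2. None passed the test over all genes; Tmem87a shows the widest gap between KO 1 and the other KO arrays.

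In the oligodendrocyte lineage list, 10 of 19 measured genes were kept, 4 of them higher and 3 lower in all 3 KO arrays than in the wild-type array, and none passed the test over all genes or adjusted over the list alone. The list was not called (median log2 difference 0.058, mean -0.073, camera adjusted p = 0.94). Nkx2-2, a transcription factor gene of oligodendrocyte precursors, gave 370.9 in the wild-type array and 132.2 ± 53.9 (SD, n = 3) in the KO arrays, a log2 difference of -1.45 (SE 0.43). Qk, which encodes a glial RNA-binding protein, differed by 0.66 (-0.025 with the mean of all its probe sets), Cspg4, the NG2 proteoglycan of precursors, by 0.49, and Aspa, the aspartoacylase of oligodendrocytes, by -0.78.

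In the GABAergic interneuron list, only 9 of 28 measured genes were kept, 1 of them higher and 3 lower in all 3 KO arrays, and none passed the test over all genes or adjusted over the list alone. The list was not called (median -0.34, camera adjusted p = 0.27). Nr2f2, a transcription factor gene of the caudal eminence, differed by -0.77, Pvalb by -0.78, the chemokine receptor gene Cxcr4 by -0.53, and Satb1 by 0.49 (-0.054 with the mean of all its probe sets). The Dlx genes, homeobox regulators of ventral forebrain neurons, were left out by the filter and were chosen after their values were seen. Dlx1 gave 2.05 in the wild-type array and 3.74 ± 0.069 (SD, n = 3) in the KO arrays. Dlx2 gave 12.7 against 33.9 ± 27.9, Dlx5 gave 11.9 against 19.3 ± 9.9, and Dlx6 gave 13.9 against 30.8 ± 29.5. The bacterial probe sets with no target reached 30.5 in the wild-type array and 21.3, 39.99 and 87.8 in KO replicates 1, 2 and 3. All 4 genes were thus at background in the wild-type array, and the signals above it were Dlx2 (30.3) and Dlx5 (28.8) in KO replicate 1 and Dlx6 (63.4) in KO replicate 2, so no difference has an exact size.

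Among neural stem cell and radial glia genes, 22 of 27 were kept, 5 of them higher and 7 lower in all 3 KO arrays (median -0.057, camera adjusted p = 0.67). Besides Hmga2, the members with the largest moderated t were Msi1, Ednrb and the X-linked gene Sox3. Ednrb and Sox3 differed by -0.67 and -1.31, and by -1.18 and -0.33 with their other probe sets. Msi1 gave 308.4 in the wild-type array and 223.2, 87.2 and 71.0 in KO replicates 1, 2 and 3, at background in replicate 3. In the pan-neuronal list, 18 of 29 genes were kept, 1 of them higher and 6 lower in all 3 KO arrays (median -0.27, camera adjusted p = 0.14). Map2, Dpysl3, Mapt and Nsg2, genes of neuronal microtubules, axon growth and vesicles, differed by -0.998, -0.68, -0.49 and -0.47. No member of either list passed the test over all genes or adjusted over the list alone.

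Among astrocyte genes, 23 of 25 were kept, and 9 of them were lower and 1 higher in all 3 KO arrays. The median was -0.22, at percentile 0.22 of matched random lists, and the list narrowly missed the threshold (camera adjusted p = 0.0508, and adjusted p = 0.62 with an estimated correlation). The estimated correlation of 0.012 was close to the preset one, so the second value reflects the 2 residual degrees of freedom of the estimate. The growth factor receptor gene Fgfr3 differed by -0.86 (SE 0.39), Mlc1 by -0.84 (SE 0.46), the hyaluronan receptor gene Cd44 by -0.51 (SE 0.31) and the gap junction gene Gja1 by -0.74 (SE 0.49). None passed the test over all genes or adjusted over the list alone. The list's median log2 difference from the wild-type array was -0.24 in KO replicate 1, -0.32 in KO replicate 2 and -0.14 in KO replicate 3. The call was made with the pair of arrays as a block (adjusted p = 0.0353) and without KO replicate 3 (adjusted p = 0.00112). With an estimated correlation it was not made in these fits, whose few residual degrees of freedom leave that test unable to decide.

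The p53 target list was the only list called (median 0.35, camera adjusted p = 0.00505), and it was higher in the KO arrays. With an estimated correlation, for which camera has 2 residual degrees of freedom, it was not called (adjusted p = 0.62). Of its 22 kept genes, 18 had a KO mean above the wild-type array, 12 were higher in all 3 KO arrays and 0 were lower in all 3, but none passed the test over all genes or adjusted over the list alone. Mdm2, the ubiquitin ligase gene that restrains p53, gave 899 in the wild-type array and 1711 ± 320 (SD, n = 3) in the KO arrays, a log2 difference of 0.90 (SE 0.34). Its other probe set differed by 0.35, at 672 in the wild-type array and 942, 1011 and 670 in KO replicates 1, 2 and 3. Apaf1, the apoptosome scaffold gene, differed by 0.59 (SE 0.31), the death receptor gene Fas by 0.79 (SE 0.45) and the mitotic spindle gene Psrc1 by 0.57 (SE 0.33). The other probe set of Apaf1 gave 214.5 in the wild-type array and 277.9, 212.2 and 63.3 in KO replicates 1, 2 and 3, at background in replicate 3. Pmaip1, 1 of the 4 members with a lower KO mean, gave 402.5 against 616, 105.6 and 72.0. It was chosen after its values were seen. The list's median was above that of every one of 10000 matched random lists (percentile 100). Extreme percentiles were also found in lists that were not called, at 0.25 for EGF and ERK, 0.33 for pan-neuronal and 0.42 for hypoxia and glycolysis. The random lists draw genes independently, so they do not allow for genes that move together. The median of the p53 target list was 0.33, 0.47 and 0.12 in KO replicates 1, 2 and 3. The list was not called without KO replicate 1 (adjusted p = 0.102) or KO replicate 2 (adjusted p = 0.0653). No list was called with an estimated correlation, whose 2 residual degrees of freedom leave little power, or by fry. With the pair of arrays as a block the p53 target list was called (adjusted p = 0.000114), but not with an estimated correlation as well (adjusted p = 0.61).

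**Figure D4:**
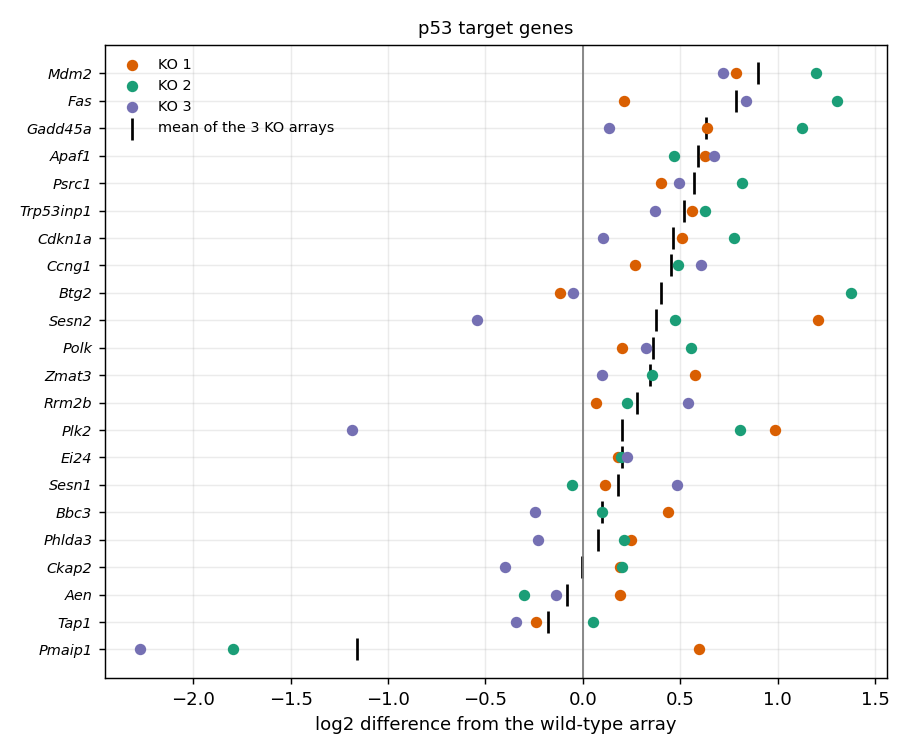
Log2 difference from the wild-type array of each array labelled KO (coloured points) and their mean (black bar) for the 22 kept p53 target genes. In 18 genes the mean is above 0, and 12 genes are higher in all 3 KO arrays; no single gene passed the test.

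The remaining 11 tested lists were not called. The interferon response list held 6 kept genes of 25 measured (camera adjusted p = 0.11). Its class I histocompatibility genes H2-K1 and H2-D1, both measured by probe sets marked for cross-hybridization, differed by -1.17 (SE 0.34) and -0.81 (SE 0.43). The camera adjusted p was 0.21 for EGF and ERK response genes, 0.30 for each of the G2/M and G1/S cell cycle lists, and 0.38 for each of the Notch, BMP and Id, Wnt and hypoxia and glycolysis lists. It was 0.48 for unfolded protein and amino acid response genes, whose median was -0.036 while their mean was 0.081 and the test pointed higher, 0.73 for mesenchyme and 0.81 for cholesterol synthesis. In all 3 KO arrays, 5 EGF and ERK response genes of 20 kept were lower and 2 higher, 8 G2/M genes of 24 lower and 3 higher, and 5 Notch genes of 17 lower and 5 higher. The leading member of the Notch list was Jag2. Other members, none of which passed the test, were Jun (-1.11, and -0.21 with its other probe set), Spry4 (202.2 in the wild-type array and 164.2, 77.6 and 26.5 in KO replicates 1, 2 and 3, at background in replicate 3, and a difference of -0.35 with its other probe set), Nek2 (-0.66), Rrm1 (-0.54), Mfng (-0.72), Smad7 (-0.52), Nkd1 (0.93), Pfkfb3 (-0.78), Chac1 (0.74), Foxc1 (0.69) and Srebf2 (-0.65). Several of these lists also held members taken by the rule that went the other way. Among them were Phlda1 (0.68), Spry2 (0.60), Cenpe (0.46), Fen1 (0.37), Bmp7 (0.47), Pfkp (0.73), Hmgcs1 (0.56), Msmo1 (0.49), Irf9 (0.48) and Fn1 (-0.73). The fit with the pair of arrays as a block compares only KO replicate 1 with the wild-type array, and there the hypoxia and glycolysis and the interferon lists were called lower and the G1/S list higher, whereas without KO replicate 1 the G1/S and the EGF and ERK lists were called lower. With an estimated correlation none of these lists was called, but the few residual degrees of freedom of these fits leave that test unable to decide. The hypoxia median was -0.92 in KO replicate 1 but 0.77 in KO replicate 3. Too few genes were kept to test 9 lists. Of the measured genes, the filter kept 0 of 10 blood genes, 3 of 22 microglial, 3 of 20 endothelial and pericyte, 2 of 11 ependymal and choroid plexus, 2 of 14 dorsal pallial and 1 of 17 caudal identity genes. It also kept 4 of 11 Hedgehog response genes, 2 of 4 sex-linked genes and 4 of 15 striatal neuron genes, among them Foxp1, which differed by 0.96 (SE 0.35) with 1 probe set and by 0.26, -0.10 and -0.41 with the 3 others above background in all 4 arrays.

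Several other list members had further probe sets above background in all 4 arrays, and these were looked up after the values were seen. Some pointed both ways. Qk differed by 0.12, -0.16 and -0.73 with its 3 others, Satb1 by -0.17 with 1 other, Gja1 by -0.63, -1.04, -0.999 and -1.70 with 4 others and by 0.49 with another, and H2-K1 by -0.83, -0.77 and 0.11. The others kept the sign but not always the size. They gave -0.98 for Fgfr3, -1.36 for Map2, -0.43 and -0.40 for Dpysl3, -0.78 and -0.052 for Mapt, -0.89 for Nr2f2 and 0.56 and 1.23 for Psrc1. They also gave -0.69 for H2-D1, -0.99 for Rrm1, -0.45 for Pfkfb3 and -0.72 for Srebf2.

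Many of the named list members went with the array pairs. In 2970 of all kept genes (39.9%), KO replicate 1 lay nearer to the wild-type array than both other KO arrays, which lay on the same side of it. Of the kept list members named above other than the sex-linked genes, each by the probe set chosen for it, this held for Olig2, Nkx2-2, Qk, Cspg4, Satb1, Msi1, Ednrb, Sox3, Map2, Dpysl3, Mapt, Fgfr3, Mlc1, Fas, Psrc1, Pmaip1, H2-D1, Irf9, Jun, Spry4, Spry2, Nek2, Cenpe, Rrm1, Nkd1, Pfkp, Fn1, Srebf2, Hmgcs1, Msmo1 and Foxp1. It did not hold for Sox2, Egfr, Hmga2, Aspa, Nr2f2, Pvalb, Cxcr4, Nsg2, Cd44, Gja1, Mdm2, Apaf1, H2-K1, Jag2, Mfng, Phlda1, Fen1, Smad7, Bmp7, Pfkfb3, Chac1 or Foxc1. This way of sorting the genes was chosen after the values were seen, and it sets no size for the gap. In Nkx2-2, for example, the differences were -0.89, -1.62 and -1.86 in KO replicates 1, 2 and 3. In Nkd1 they were 0.75, 1.28 and 0.77, so KO replicates 1 and 3 hardly differed.

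Genes near the targeted locus were examined because a targeted allele can alter its neighbours or carry flanking sequence. Of 49 kept genes within 10 Mb of Olig1 on chromosome 16, 0 passed the test and 1 had an unadjusted p under 0.05, against 167 of 7387 other genes (two-sided Fisher's exact test, p = 1). Their median log2 difference was 0.10, at percentile 93.5 of matched random lists, and was 0.10, 0.11 and 0.10 in KO replicates 1, 2 and 3.

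The KO arrays also differed from one another in single genes. The 5 genes with the largest SD over the KO arrays were Xist, Eif2s3y, Tmem87a, Selenbp1 and Sh3d19. Selenbp1, a selenium-binding protein gene, gave 40.1, 376 and 756 in KO replicates 1, 2 and 3 against 222.6 in the wild-type array, and its other probe set gave 55.0, 313 and 650 against 231.2. Sh3d19 gave 270.2, 121.7 and 7.67 against 257.3, and 1 of its other 3 probe sets gave 104.02, 86.9 and 55.6 against 62.0, both at background in KO replicate 3.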

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

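The tests of explanations in this part were chosen after the results were seen, except quantile normalization and the count for each array on its own, which were planned. Control probe sets outside the gene comparison carried signal in 2 arrays above the wild-type array. The median signal of the 18S ribosomal RNA controls was 946 in KO replicate 2 and 2823 in KO replicate 3, against 4.64 in the wild-type array. The spike-in controls stood at 1.93 times the wild-type array in KO replicate 2 and 2.87 times in KO replicate 3.

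The first pattern is that the wild-type array was nearest to KO replicate 1, with which it also shares the sex-linked genes and the array controls. The shape of the signal distribution of KO replicate 3 is argued against as the source of its distance, since 168 genes still stood 2-fold apart from all other arrays after quantile normalization, against at most 23 in any other array. KO replicate 3 also had the highest 3'/5' ratio of beta-actin (1.82), though not of Gapdh (0.842), and the highest bacterial signal with no target (87.8). As deposited, 153 of its 173 genes lay below all other arrays. Whether RNA integrity or background lies behind its distance was not tested. A difference between the 2 pairs of arrays stays open. It goes with 1248 genes at an unadjusted p under 0.05 in limma between the pairs, against 54 and 249 for the other splits into pairs. Yet the SD of log2 differences between KO replicates 2 and 3 (0.51) exceeded that between KO replicates 1 and 2 (0.46) by 0.048. It also exceeded that between KO replicate 2 and the wild type (0.49). These are single values with no spread between arrays. The count of 1248 thus does not separate a difference between the pairs from KO replicate 3 standing apart alone, with 173 genes 2-fold from all other arrays. Whether KO replicate 1 holds wild-type RNA stays open, because the Olig1 signal does not check the genotype labels. As deposited, that signal differed from the wild type by -0.99 log2 units in KO replicate 1 and was not lower in KO replicate 3. With 4 arrays the splits are too few for a share under 0.05: set against the other 3, 3 of the 4 arrays, the wild type included, had at least the 21 genes of the wild type, and the highest other had 173, while sex and array processing cannot be told apart within the pairs, because both change between the same arrays.

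The second pattern is the Olig1 signal of the arrays labelled KO. Scaling bears on whether KO replicate 3 lies above the wild type. Its log2 difference was 0.17 as deposited and -0.20 under quantile normalization, where all KO arrays lay below the wild type. With medians set equal it stayed above, at 13.10 against 12.88. Under quantile normalization the Olig1 value of KO replicate 3 stayed within 0.20 log2 units of the wild type. This argues against a different shape of its signal distribution as the reason why the 2 values are near. Both scalings set the bulk of the arrays equal. A scaling on the spike-in controls, at 2.87 times the wild-type array in KO replicate 3, was not run, so scaling as such stays open. The RNA of these arrays may hold the sequence that the probe set measures, because the lowest ratio of Olig1 to the highest bacterial probe set with no target was 97.3. That would occur both with an allele that keeps the probed part of the transcript and with a wrong label, and no value here separates these.

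The third pattern is the higher signal of p53 target genes in the KO arrays. The data argue little for a difference between the 2 pairs of arrays but do not exclude it: the pairs differed by a median of 0.17 (adjusted p = 0.72), and with the pair as a block the median was 0.33 and the list was called (adjusted p = 0.000114), but not with its estimated correlation taken as known (adjusted p = 0.0833). This was the third form of the test, after the list's percentile between the wild type and KO replicate 1 (100) and the number of tested lists outside the central 95% of random lists there (10 of 17). A shift of correlated genes that the preset correlation leaves out also stays open and would be enough: with the estimated correlation of 0.089 taken as known the adjusted p was 0.0866, and with its 2 residual degrees of freedom it was 0.62. The list may thus reflect 1 unusual culture, the single wild-type one, as well as genotype, and the design holds no second wild-type array to decide.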

How the results depend on the processing

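No paired analysis was possible because the labels give the single wild-type array no number shared with a KO array; the block of array pairs was chosen after seeing the data and is not a pairing from the labels. Counts of 0 genes higher and 0 lower held under every alternative run except without KO replicate 1, where 1 was higher (Eif2s3y, at background in the wild-type array) and 1 lower (Tmem87a, at background in KO replicates 2 and 3), each at an adjusted p of 0.0368; leaving out each KO array gave 0 to 1 in each direction. Of 1016 pairs of an alternative and 1 of 63 named genes, 1004 kept the direction without a call. Pmaip1 and the list members given as going the other way were not among the 63. The direction was reversed for Selenbp1 with the pseudocount divided by 4 (-0.031), a floor at the 20th percentile (-0.047) and the array pair as a block (-2.12), and it ranged from -0.70 to 1.21 when an array was left out. It was reversed with the mean of all probe sets for Qk (-0.025) and Satb1 (-0.054), and with the block for Olig2 (0.21), Rrm1 (0.11) and Sh3d19 (0.067). The Olig1 difference stayed below 0 in every setting run, from -0.99 with the block to -0.31 without KO replicate 1. The count of lists called higher, 1 in the main setting, was 0 with no filter (p53 targets, adjusted p = 0.0854), the mean of all probe sets (0.0518), an estimated correlation (0.621) and fry (0.915), 2 with the block, 0 with the block and an estimated correlation, and 0 to 1 when an array was left out. The count called lower, 0 in the main setting, was 1 with quantile normalization, the pseudocount divided by 4 or a prior with trend (astrocyte genes each time), 2 with the mean of all probe sets (astrocyte and Notch), 3 with the block (astrocyte, hypoxia and interferon), and 0 to 3 when an array was left out. The cause was not tested. The p53 target list was higher in all 17 alternatives that used camera and called in 11, with adjusted p from 1.37e-05 to 0.621; fry asks another question, whether the genes of the list alone move one way. The 21 genes with the wild-type array 2-fold from every KO array became 155 with no filter and 8 with 4 times the pseudocount. The median near Olig1 was 0.15 (percentile 94.1) within 2 Mb and 0.13 (percentile 98.3) within 20 Mb. Scaling moved the median of all genes by at most 0.02. Signal over background limits dim genes such as the Dlx genes, and the robust prior does not enter camera.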

Other observations

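The tests in this part were chosen after the data were seen. Transcripts of the hypoxia and glycolysis list spread widely over the KO arrays. Relative to the wild-type array, the median over its 19 kept genes was -0.92 in KO replicate 1, -0.24 in KO replicate 2 and 0.77 in KO replicate 3. Vegfa, the vascular growth factor gene, gave 1339 in the wild-type array and 478, 894 and 1778 in KO replicates 1, 2 and 3, and Egln3, an oxygen-sensing prolyl hydroxylase gene, gave 737 and 243, 453 and 922. The other probe sets of these 2 genes had KO replicate 3 below the wild-type array, at 557 and 130.4, 199.0 and 354 for Vegfa and 372 and 132.1, 192.2 and 245.4 for Egln3. The list's correlation estimated over the arrays was 0.89.

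Between the 2 pairs of arrays, 3 genes passed limma's test, Eif2s3y, Xist and Tmem87a (adjusted p = 0.00949, 0.0411 and 0.0458), of which Eif2s3y and Xist had served to mark the pairs. In the same test 1248 genes had an unadjusted p under 0.05, against 54 and 249 for the other 2 splits of the arrays into pairs. That count does not separate a difference between the pairs from KO replicate 3 standing apart alone. The X-linked genes Kdm5c and Eif2s3x were lower in the pair with high Y-linked signal by 1.51 and 0.84 log2 units (-1.51 and -0.84), without passing (adjusted p = 0.22 for each). Of the other X-linked genes with a Y-linked partner that were tested, Kdm6a differed by 0.10 (adjusted p = 0.87) and Ddx3x by -0.17 (adjusted p = 0.69), each with the probe set chosen for the gene. The other probe set of Kdm6a differed by -1.01, with signals of 278 and 344 against 160.1 and 133.6, and the other 2 of Ddx3x by -0.70 and -0.27. In camera with the preset correlation, G1/S cell cycle genes (median -0.49, adjusted p = 0.000196) and EGF and ERK response genes (-0.53, adjusted p = 0.00391) were lower in the mean of KO replicates 2 and 3 than in that of the other pair. Hypoxia and glycolysis genes were higher (0.69, adjusted p = 0.000257). Relative to the wild-type array, the G1/S median was 0.18, -0.30 and -0.39 in KO replicates 1, 2 and 3. The EGF and ERK median was 0.23, -0.06 and -0.64, and the hypoxia median -0.92, -0.24 and 0.77. For hypoxia genes, KO replicate 2 thus lay below the wild-type array, and the pair means do not describe it. With an estimated correlation none of these lists was called (adjusted p = 0.90 for each), but few residual degrees of freedom leave that test unable to decide.

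Several genes high on the list of differences lie on chromosome 17, among them Airn, Zdhhc14, Lix1, Dnah8 and H2-K1, and a segment of another strain was a candidate explanation. On chromosome 17, 11 of 367 genes had an unadjusted p under 0.05, against 157 of 7059 elsewhere (two-sided Fisher's exact test, p = 0.36). The fullest run of 100 neighbouring genes held 7 such genes, on chromosome 2, and a run as full arose in a share of 0.84 of 10000 random gene orders. The fullest run on chromosome 17 held 6. Chance placement is enough for these counts, which cover all genes at an unadjusted p under 0.05. They do not test the few largest differences that prompted the question, so a segment of another strain is not excluded.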
